A study of Mus musculus with 9 samples.

How the data were processed

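The series followed mouse embryonic fibroblasts of the C57Bl/6 strain through reprogramming by plasmid-borne Oct4, Sox2, Klf4 and c-Myc. Hairpins were carried by a retroviral vector, the cells grew in embryonic stem cell medium with LIF, and total RNA was extracted with TRIzol and sequenced on an Illumina instrument. The labels give 9 libraries, 1 for each of 3 arms (luciferase, Hnrnpk and lincRNA-p21 hairpins) on each of days 6, 9 and 12, and call each library merged replicates. How many replicates were merged, and how, is not given in the sources used here.

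The deposited table holds 12550 genes by 9 libraries, in a unit the labels call signal. The authors' notes name RSEM 1.2.12, Bowtie 1.0.1 and the genome build mm10, without saying what each did. How the signal was scaled, and whether the table is complete, is not given in the sources used here. Per the deposited values, the signal moves in steps of 0.5, 62.8% of values are whole, and the column totals differ by 0.025%. All columns share a highest value of 118715, and a lower block of values lies between 62240 and 62366. All 16 distinct values between that block and the highest are midpoints of the highest and another value. Such a pattern arises when each column is the mean of a pair of columns set to 1 shared scale of values. Counts of reads were therefore not available here, count-based tests were not used, and the depth per library is unknown. No gene has a highest value under 32.5 or a mean under 11.6, so genes silent in every library are absent from the table, and 12512 genes are above 0 in every library. Gene names came from the table, and coordinates and gene types from GENCODE M21, which holds 12470 of the gene identifiers and lacks 80. There were 23 symbols shared by more than 1 entry, which were kept apart by identifier, and 0 value columns belonged to no library.

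Values were used as deposited, with 10 added before the log2. Genes with a mean of at least 20 over the libraries were tested (12541, with 9 below). Tests were made in R 4.3.3 with limma 3.58.1, in a model with a term for each arm and each day (4 residual degrees of freedom, 4.46 prior and 8.46 in total), moderated with an intensity trend and adjusted by Benjamini-Hochberg at 0.05. The arms were compared in pairs and as the mean of both knockdowns against control, and the days in pairs. Slopes of an arm's effect over the days were tested in a model with 2 residual degrees of freedom, in units of 3 days. With 1 library per arm and day, the spread that the tests measure is how far an arm's difference varies between days, or a day's between arms. Variation between replicates of the same arm and day could not be measured. Within each day, differences of at least 2-fold were counted with no test.

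Gene lists were fixed before the data were examined: reprogramming factors, pluripotency, epithelial, fibroblast, keratinocyte, p53 targets, senescence, cell cycle, apoptosis, H3K9 and DNA methylation machinery, germline, early lineage, interferon-stimulated, glycolysis, oxidative phosphorylation, ribosomal proteins, hnRNP paralogs, macrophage, endothelial, muscle, neural, adipocyte, histones and mitochondrially encoded genes. Lists with at least 5 members in the table were tested with camera at a preset correlation of 0.01 between genes, again with an estimated correlation, and with fry, each adjusted over the lists. With an estimated correlation camera uses only the 4 residual degrees of freedom, so a lost call can reflect low power. Beside each count of called members stands the count when p is adjusted over that list alone. The SE of a median over genes reflects the spread among those genes, not between libraries. Genes of the same library are not independent replicates, so such an SE may be too small.

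The genes named were chosen by a rule written before the data were examined. It takes the hairpin targets and Cdkn1a, and the 8 genes with the largest change each way among those called and changed the same way on every day or in every arm. Where fewer than 5 passed in a direction it takes the 5 with the largest difference on their weakest day. From each list described it takes up to 4 members with the largest difference. The result of 1 gene that the rule selects is not reported here. Genes named only by clone or model number, small RNAs and pseudogenes were counted but not named under the parts of the rule that rank all genes. Genes named for the time slopes and between the knockdown arms followed the same list rule.

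The agreement between the knockdown arms was set against 100 simulated draws in which the arms were unchanged and shared the same controls. The tests were tested on simulated data, pooled over several draws to 300 changed genes of each size. They recovered 90.7% to 93% of changes of 1 and 99% to 99.7% of changes of 2 on the log2 scale. Of the called genes 5.63% to 7.52% were false. The simulated spread was independent between genes, without the shared shifts that real libraries can hold, so these rates may not carry over to the deposited data. The rates also depend on how many genes change in a draw, which need not match the deposited data. A small number of called genes therefore does not show that changes of this size are absent.

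Alternatives fixed before the data were examined were an added value of 1 or 50, no filter or a filter at 100, quantile normalization, median-ratio rescaling, no intensity trend, robust moderation, no day or arm term, only the 6 libraries compared, each day or library left out, fry or an estimated correlation for lists, Spearman rho for the agreement, and a fold of 1.5 within days. Nothing was left out of the table but the genes under the filter.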

Results

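Mouse embryonic fibroblasts carrying the reprogramming factors Oct4, Sox2, Klf4 and c-Myc were sampled on days 6, 9 and 12 of their conversion to induced pluripotent cells. The cells carried a short hairpin RNA against luciferase (control), against Hnrnpk, or against lincRNA-p21 (gene Trp53cor1). Each of the 3 arms has 1 library per day, 9 libraries in all, and the labels call every library merged replicates. The table holds 12550 genes, the column totals differ by 0.025% after the authors' scaling, and the number of reads behind each library is unknown. A comparison of arms therefore sets 3 libraries against 3, paired by day. Differences are log2 values with 10 added to each value first, so they understate the change of genes with low values. The p-values measure only how the arm differences spread over the days, because the replicates were merged before deposition.

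The knockdowns were read first, since every comparison of arms rests on them. Trp53cor1, the p53-induced non-coding RNA upstream of Cdkn1a, had values of 286.5, 237 and 250 on days 6, 9 and 12 in the control arm. In the lincRNA-p21 arm they were 90.5, 122 and 97, a difference of -1.25 (SE 0.15), which did not pass the test (limma with Benjamini-Hochberg, adjusted p = 0.0603). Trp53cor1 fell in the Hnrnpk arm as well, to 131, 137 and 119.5 (-0.94, SE 0.15, limma adjusted p = 0.00752). The fall in the lincRNA-p21 arm was the larger and had the same SE. Its adjusted p was higher only because the adjustment over all 12541 genes differs between the contrasts. The knockdown arms differed from each other by -0.31 in Trp53cor1 (limma adjusted p = 0.318). Hnrnpk, which encodes an RNA-binding and transcription regulator, had values of 31243, 26944 and 23376 in the control arm and 11349, 17016 and 12793 in its own arm, a fall (-1, SE 0.16, limma adjusted p = 0.00824). In the lincRNA-p21 arm Hnrnpk stood at 31142, 29972 and 27873, a difference of 0.13 (limma adjusted p = 0.738).

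Cdkn1a, the cell cycle inhibitor gene next to Trp53cor1 on chromosome 17, differed little between the arms. Its values were 12063.5, 11815 and 11815 in the control arm, 15118, 11172.5 and 11221 in the Hnrnpk arm, and 14594, 11286.5 and 11176 in the lincRNA-p21 arm. The differences from control were 0.06 in the Hnrnpk arm (limma adjusted p = 0.794) and 0.04 in the lincRNA-p21 arm (limma adjusted p = 0.9). Both turned negative without day 6, at -0.08 and -0.07.

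**Figure D1:**
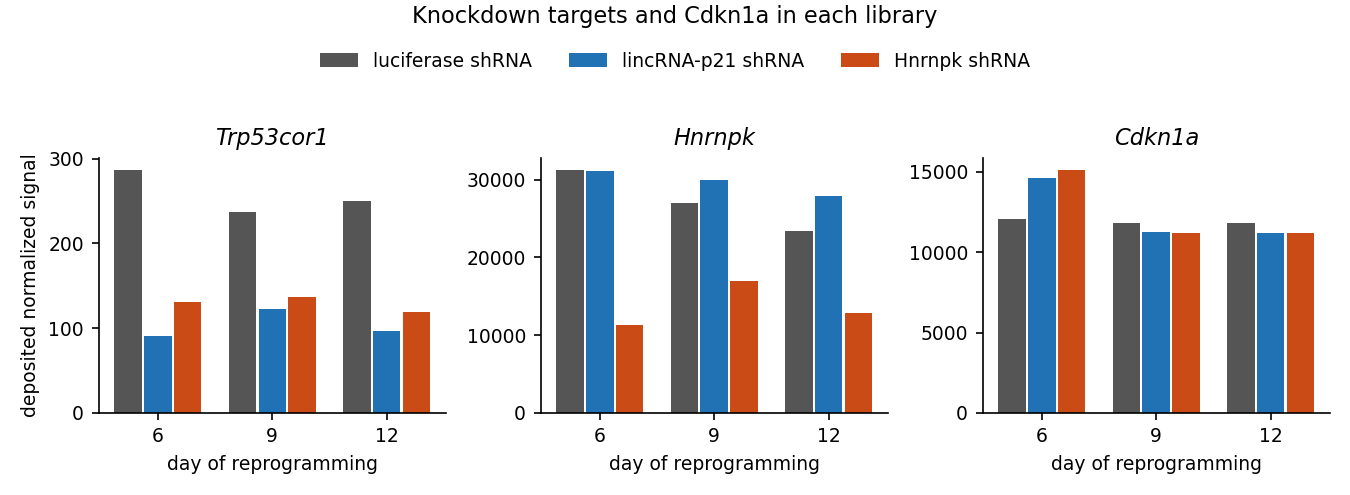
Deposited values of the targeted genes Trp53cor1 and Hnrnpk and of the neighbouring gene Cdkn1a in every library, by arm and day. Each bar is 1 library of merged replicates.

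A principal component analysis of the log2 values placed day before arm. The first component held 63.8% of the variance and set the day 6 libraries (-48.7 to -57.5) apart from those of days 9 and 12 (8.3 to 42.2). The next component held 16% and ordered the arms. The control libraries lay at -19.2 to -23.6, the lincRNA-p21 libraries at -6.4 to 2.4 and the Hnrnpk libraries at 19 to 29.8.

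**Figure D2:**
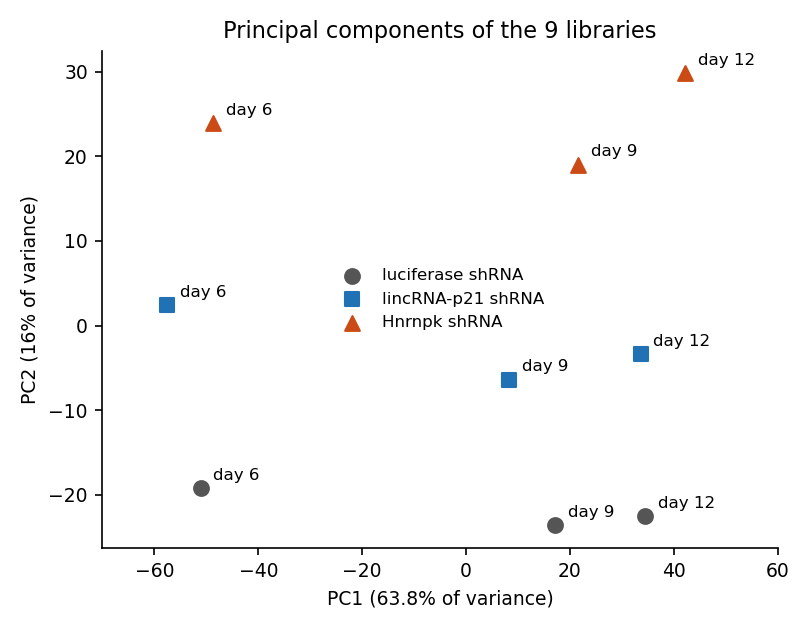
First and second principal components of the log2 values of the 9 libraries, coloured by arm and marked by day.

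The comparison of the Hnrnpk and control arms asked what loss of Hnrnpk does to expression during reprogramming. Each target has 1 arm, so other effects of a hairpin cannot be told apart from loss of its target. With Hnrnpk reduced, 16 of 42 pluripotency, 12 of 34 epithelial, 12 of 15 keratinocyte and 14 of 21 interferon-stimulated genes rose. These lists lay above other genes by camera with a preset correlation, and none of those calls held with an estimated correlation. Among the largest rises were those of Utf1, a chromatin factor of undifferentiated embryonic cells, and Tdgf1, a Nodal co-receptor of pluripotent cells. Krt5 and Ivl, which encode a basal keratin and a cornified envelope protein of skin, rose with them, while Myc, Klf4 and Sox2 fell. In all, 1570 of 12541 genes passed (limma with Benjamini-Hochberg at 0.05), 700 higher and 870 lower in the Hnrnpk arm. Of these, 385 differed by at least 2-fold. Leaving out day 9 or day 12 gave 25 and 367 genes and leaving out day 6 gave 3001. Leaving out 1 library gave 559 (control day 9), 603 (Hnrnpk day 9), 759 (Hnrnpk day 12), 967 (lincRNA-p21 day 9) or 987 (control day 12), and the other libraries gave up to 2045.

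Among genes changed in the same direction on every day, the largest rises in the Hnrnpk arm by limma were Utf1 (3.07, SE 0.65, adjusted p = 0.0196), Krt5 (3.04, SE 0.51, adjusted p = 0.0087), Lrp2 (3.02, SE 0.16, adjusted p = 0.000179), Nkx2-3 (2.94, SE 0.19, adjusted p = 0.00062), Tdgf1 (2.70, adjusted p = 0.0131), Fabp3 (2.70, adjusted p = 0.00368), Mycn (2.60, adjusted p = 0.0212) and Ivl (2.43, adjusted p = 0.00357). Lrp2, an endocytic receptor of absorptive epithelia, went from 121, 65 and 100 in the control arm to 1409, 459.5 and 863, which is 8.13-fold. Nkx2-3, a homeobox factor of gut and spleen mesoderm, stood at 15, 18 and 14.5 in the control arm, near the added 10, and at 196, 176.5 and 192 in the Hnrnpk arm. In the lincRNA-p21 arm Nkx2-3 stayed at 15, 17 and 11.5. On day 6 Utf1 stood at 3 in the control arm and 10 in the Hnrnpk arm, and Tdgf1 at 7 and 20. In the control arm Krt5 was at 8 on day 6, and Ivl at 8.5, 7 and 17.5 on days 6, 9 and 12. The sizes of these differences therefore depend on the added 10. The largest falls by limma, again among genes changed in the same direction on every day, were Kctd12 (-3.21, SE 0.72, adjusted p = 0.0234), Arhgap36 (-2.23, adjusted p = 0.0011), Sost (-2.18, adjusted p = 0.00557), Begain (-2.02, adjusted p = 0.000472), Prkcb (-1.94, adjusted p = 0.00129), Htra3 (-1.71, adjusted p = 0.00563), Negr1 (-1.69, adjusted p = 0.00259) and Ndufa4l2 (-1.68, adjusted p = 0.0391). These encode, in order, a GABA-B receptor subunit, a Hedgehog pathway activator, the Wnt antagonist sclerostin, a postsynaptic scaffold partner, a protein kinase C, a secreted protease, a neuronal adhesion protein and a hypoxia-induced mitochondrial protein. Arhgap36 went from 2628, 1516.5 and 600.5 to 390.5, 395.5 and 136.5, and stood at 2005.5, 1549.5 and 765 in the lincRNA-p21 arm. Kctd12 was at 0.5, 77.5 and 0.5 in the Hnrnpk arm against 239, 306.5 and 86.5 in the control arm, and at 1.5, 291.5 and 56.5 in the lincRNA-p21 arm.

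Of 42 pluripotency genes, 16 rose in the Hnrnpk arm and none fell (25 and 0 when adjusted over the list alone). Besides Utf1, Tdgf1 and Mycn, the rises were led by Dppa5a, an RNA-binding protein of embryonic stem cells (3.22, limma adjusted p = 0.0442), and Lin28a, which blocks let-7 maturation (2.82, limma adjusted p = 0.0451). The list was higher than other genes by camera (adjusted p = 2.19e-10, and adjusted p = 0.471 with an estimated correlation), with a median of 0.86. The median was 0.02 on day 6, 1.22 on day 9 and 1.42 on day 12, so the excess belonged to the later days, and fry did not call the list (adjusted p = 0.105).

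Epithelial and skin genes were higher on every day. In the epithelial list of 34 genes 12 rose and 1 fell (21 and 1 when adjusted over the list alone), with a median of 0.44 (camera adjusted p = 2.61e-07, adjusted p = 0.315 with an estimated correlation). The rises were led by the tight junction genes Cldn6 (2.36, limma adjusted p = 0.0195) and Cldn4 (1.2, limma adjusted p = 0.0044), the simple keratin Krt18 (2.14, limma adjusted p = 0.0158), and E-cadherin, Cdh1 (1.11, limma adjusted p = 0.00542). In the keratinocyte list of 15 genes 12 rose and none fell (14 and 0 when adjusted over the list alone), with medians of 0.80, 0.73 and 0.83 on days 6, 9 and 12. Its camera adjusted p was 2.17e-10, with adjusted p = 0.314 with an estimated correlation. Besides Krt5 and Ivl it held Krtdap, a keratinocyte differentiation peptide (1.42, limma adjusted p = 0.034), and Sfn, the epithelial 14-3-3 sigma (1.18, limma adjusted p = 0.00143).

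Interferon-stimulated genes rose in the Hnrnpk arm, 14 of 21 with none falling (17 and 0 when adjusted over the list alone). The medians were 0.59, 0.78 and 1.03 on days 6, 9 and 12 (camera adjusted p = 2.19e-10, adjusted p = 0.387 with an estimated correlation). They included the ubiquitin-like modifier Isg15 (2.39, limma adjusted p = 0.00852), the guanylate-binding protein Gbp2 (1.99, limma adjusted p = 0.00526), the transcription factor Irf7 (1.89, limma adjusted p = 0.00563) and the antiviral protein Oasl2 (1.69, limma adjusted p = 0.0159). Gbp2 and Oasl2 have close paralogs, so their values may hold reads of other family members.

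Of 37 p53 targets, 9 rose and none fell (10 and 0 when adjusted over the list alone; median 0.21; camera adjusted p = 0.000435, adjusted p = 0.471 with an estimated correlation). Gdf15, a stress cytokine (1.79, limma adjusted p = 0.00407), Pmaip1, the pro-apoptotic Noxa (1.27, limma adjusted p = 0.00368), the DNA damage gene Gadd45a (1.10, limma adjusted p = 0.00272) and the ephrin receptor Epha2 (0.88, limma adjusted p = 0.0143) led them, and Cdkn1a was not among them. In the senescence and secretory list 9 of 22 rose and 1 fell (11 and 2 when adjusted over the list alone; median 0.39; camera adjusted p = 0.00127, adjusted p = 0.415 with an estimated correlation). The urokinase Plau (1.45, limma adjusted p = 0.0038), the chemokine Ccl2 (1.36, limma adjusted p = 0.00357) and the cell cycle inhibitor Cdkn2b (1.09, limma adjusted p = 0.0134) rose.

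The neural, fibroblast and muscle lists did not differ from other genes by camera, although members of each changed. The neurofilament genes Nefl (2.33, limma adjusted p = 0.000117) and Nefm (2.12, limma adjusted p = 0.00342) and the neuronal tubulin Tubb3 (1.15, limma adjusted p = 0.00462) rose, 3 of 12 neural genes with none falling (3 and 2 when adjusted over the list alone; median 0.21; camera adjusted p = 0.114). Syt1, a synaptic vesicle protein, was at -0.39 (limma adjusted p = 0.0662). Of 45 fibroblast genes 5 rose and 4 fell, with the same counts when adjusted over the list alone (median 0.07; camera adjusted p = 0.344). The contractile genes Cnn1 (1.31, limma adjusted p = 0.0239) and Tagln (1.03, limma adjusted p = 0.0201), N-cadherin, Cdh2 (1.22, limma adjusted p = 0.00227), and the collagen cross-linker Lox (1.15, limma adjusted p = 0.0314) were among the rises. Without day 6 the fibroblast median was -0.08. Of 5 muscle genes, Des (1.73, limma adjusted p = 0.00286) and Acta1 (1.65, limma adjusted p = 0.0148) rose and Tnni1 fell (-1.30, limma adjusted p = 0.0148), while Mylpf was at 1.19 (limma adjusted p = 0.134). The list gave 3 and 1 when adjusted over the list alone, with a median of 1.19 (camera adjusted p = 0.114).

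The test fry asks whether a list's genes move on balance in 1 direction and makes no comparison with other genes. In the Hnrnpk arm it called the keratinocyte and neural lists (adjusted p = 0.00566 for each), the epithelial and interferon lists (adjusted p = 0.0129 for each) and the senescence list (adjusted p = 0.0332), all upward. No camera call in any comparison held with an estimated correlation. That form of camera uses only the 4 residual degrees of freedom and so has little power here. In the lincRNA-p21 arm the neural list lost its call under it (camera adjusted p = 0.00898, then 0.332). Its estimated correlation was -0.003, under the preset 0.01. A lost call therefore need not come from correlation between genes.

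The series concerns H3K9 and CpG methylation at pluripotency promoters, so the genes of that machinery were read as a list. Of 29 genes none rose and 2 fell in the Hnrnpk arm (0 and 2 when adjusted over the list alone), with a median of -0.13 (camera adjusted p = 0.116) that stood at 0.02 without day 6. The H3K9 demethylase Kdm4b (-0.48, limma adjusted p = 0.0291) and the DNA methyltransferase Dnmt3a (-0.45, limma adjusted p = 0.0332) fell. Dnmt3b, the methyltransferase of early embryonic cells, was at 2.22 (limma adjusted p = 0.0551) and the 5-methylcytosine oxidase Tet2 at -0.68 (limma adjusted p = 0.085). Of the germline list, drawn up for genes silenced by such methylation, only 4 were in the table. Not all of these need be silenced by it in these cells. The meiotic cohesin genes Smc1b (-1.30, limma adjusted p = 0.00743) and Stag3 (-0.87, limma adjusted p = 0.0268) fell, with Sycp1 at -0.15 and Ddx3y at 0.10. The list gave 2 falls when adjusted over the list alone, with a median of -0.51.

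The reprogramming factors were lower in the Hnrnpk arm, in values that join plasmid and chromosomal transcripts. Myc (-0.87, limma adjusted p = 0.0148), Klf4 (-0.81, limma adjusted p = 0.00948) and Sox2 (-0.48, limma adjusted p = 0.0201) fell, and Pou5f1, which encodes Oct4, was at -0.60 (limma adjusted p = 0.0885). All 4 passed when adjusted over the list alone. Pou5f1 read 44876 in all 3 arms on day 9, which columns set to a shared scale of values can give.

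With each library left out in turn, the Hnrnpk calls of Utf1, Krt5, Tdgf1, Mycn, Kctd12, Cldn6, Krt18, Krtdap, Oasl2, Epha2, Cdkn2b, Cnn1, Lox, Tagln, Acta1, Tnni1, Stag3, Myc and Sox2 were lost at least once. Those of Dppa5a, Lin28a, Ndufa4l2, Kdm4b and Dnmt3a were kept in only 2 of 9.

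The comparison of the lincRNA-p21 and control arms asked the same of lincRNA-p21. Nefl, the light chain of neurofilaments, rose 2.26-fold in the lincRNA-p21 arm. It was the only gene of 12541 to pass (limma with Benjamini-Hochberg, 1.18, SE 0.11, adjusted p = 0.0304), with 1 higher and 0 lower. Nefl went from 325.5, 192 and 158.5 to 808.5, 459 and 335.5. At unadjusted p under 0.05 there were 1730 genes where 627 would be expected by chance, and 47 genes had a limma adjusted p under 0.1. Leaving out day 6, control day 6 or Hnrnpk day 6 gave 175, 92 and 71 genes. Leaving out day 9, day 12 or any of the other libraries except Hnrnpk day 12 gave 0 by limma, with 618 genes at unadjusted p under 0.05 without day 9.

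Genes below the threshold in the lincRNA-p21 arm are given as values, chosen as those with the largest difference on their weakest day. The higher ones, by limma, were Tdgf1 (2.36, adjusted p = 0.113), Cnn1 (1.55, adjusted p = 0.105), Gbp2 (1.46, adjusted p = 0.109), the immunoproteasome subunit Psmb8 (1.34, adjusted p = 0.115) and the Wnt receptor Fzd10 (1.19, adjusted p = 0.0681). The lower ones were the RNA-binding zinc finger gene Zfr2 (-1.27, adjusted p = 0.0728), Trp53cor1 itself, the kinase gene Aatk (-1.16, adjusted p = 0.0603), the membrane protein gene Sertm1 (-1.10, adjusted p = 0.102) and the matrix protein gene Vit (-0.92, adjusted p = 0.0728) (limma). The remaining neural genes at the top of their list were Gap43, of growing axons (1.52, limma adjusted p = 0.0974), Tubb3 (1.24, limma adjusted p = 0.0603) and Nefm (1.18, limma adjusted p = 0.113). The 12 neural genes held 1 rise and no fall (4 and 0 when adjusted over the list alone; median 0.10; camera adjusted p = 0.00898, adjusted p = 0.332 with an estimated correlation), and theirs was the only list called by fry (adjusted p = 0.0277).

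The pluripotency list was higher in the lincRNA-p21 arm and the epithelial list was lower, with no single member passing in either. Pluripotency genes had a median of 0.53, from 0.02 on day 6 to 0.59 on day 9 and 1.28 on day 12 (0 of 42 called, 7 higher and 1 lower when adjusted over the list alone; camera adjusted p = 2e-05, adjusted p = 0.868 with an estimated correlation). Utf1 was at 2.25 (limma adjusted p = 0.199), Mycn at 2.14 (limma adjusted p = 0.16) and Lin28a at 1.94 (limma adjusted p = 0.318). Without day 12 the median was 0.28 and the camera call was lost (adjusted p = 0.068). The epithelial list had a median of -0.26 (0 of 34 called, 0 higher and 6 lower when adjusted over the list alone; camera adjusted p = 7.87e-09, adjusted p = 0.332 with an estimated correlation). Krt7, a keratin of simple epithelia, was at -0.65 (limma adjusted p = 0.0814), the claudin gene Cldn3 at -0.75 (limma adjusted p = 0.113), the desmosome gene Dsp at -0.67 (limma adjusted p = 0.253) and Cldn6 at 0.85 (limma adjusted p = 0.497). None of 15 keratinocyte genes was called, also when adjusted over the list alone, and their median was 0 (camera adjusted p = 0.692).

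Interferon-stimulated genes had a median of 0.27 in the lincRNA-p21 arm (0 of 21 called, 2 higher when adjusted over the list alone; camera adjusted p = 0.000583, adjusted p = 0.847 with an estimated correlation). Irf7 was at 1.06 (limma adjusted p = 0.15), Isg15 at 1 (limma adjusted p = 0.318) and Oasl2 at 0.90 (limma adjusted p = 0.306). Of the reprogramming factors, Myc was at -0.60, Pou5f1 at -0.48, Sox2 at -0.30 and Klf4 at -0.14, with none called (2 lower when adjusted over the list alone; list median -0.39).

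Whether the knockdowns act on the same genes was asked directly. Across all genes the differences of the lincRNA-p21 and Hnrnpk arms from control correlated with r = 0.664 and a covariance of 0.0726. The control libraries are shared, and simulated data with unchanged arms gave r = 0.502 (0.473 to 0.54 over 100 draws) and a covariance of 0.0132, so part of the correlation may come from the shared controls. Pairs of differences from separate days share no library, and of 6 such pairs 5 were positive, with r from -0.04 to 0.54 and a median of 0.235. The simulated data hold only the spread between days. A shift of the control arm kept on all days would raise the correlation in either case. It cannot be told apart from a shared effect of the knockdowns. The sign was the same in both arms for 72.9% of genes, against 66.7% in the simulated data. The 2 lists of called genes shared 1 gene, Nefl, where independent lists would share 0.056, and part of that excess may come from the shared controls. The mean of both knockdown arms against control gave 787 genes by limma with Benjamini-Hochberg, 375 higher and 412 lower. Of these, 356 and 394 were also called in the Hnrnpk arm alone, where independent lists would share 20.9 and 28.6, and these contrasts use the same libraries, so part of the excess comes from that. Nefl (1.75, limma adjusted p = 0.000373) and Tdgf1 (2.53, limma adjusted p = 0.0192) rose and Trp53cor1 (-1.10, limma adjusted p = 0.00799) fell in this mean, and Hnrnpk was at -0.43 (limma adjusted p = 0.111). With each library left out in turn Tdgf1 kept its call in only 5 of 9, and Trp53cor1 lost its call without control day 9 (limma adjusted p = 0.0621). Leaving out day 9, day 12 or day 6 gave 2, 39 and 1965 genes, and leaving out 1 library gave from 5 (control day 9) to 1374 (Hnrnpk day 6).

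The knockdown arms were then set against each other to see where they part. In the lincRNA-p21 arm 20 of 34 epithelial and 9 of 15 skin genes were lower. Neither list's camera call held with an estimated correlation. Krt18, the claudin genes Cldn7 and Cldn4, and the skin genes Krt5 and Ivl led the difference, and Gdf15, a cytokine gene among the p53 targets, was lower too. The test called 409 genes (limma with Benjamini-Hochberg), 213 higher and 196 lower in the lincRNA-p21 arm. Of the higher genes 175 were among those that fell in the Hnrnpk arm against control, and of the lower genes 154 were among those that rose there. Independent lists would share 14.8 and 10.9, and both contrasts use the same Hnrnpk libraries, so part of the excess comes from that. Without day 9 or day 12 limma called 0 genes (1098 and 1654 at unadjusted p under 0.05) and without day 6 it called 649. Leaving out 1 library gave 4, 7 and 14 genes (lincRNA-p21 days 6, 9 and 12), 9 and 92 (Hnrnpk days 9 and 12), 134 (control day 9) and 959 (control day 6).

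In the epithelial list 20 of 34 genes were lower in the lincRNA-p21 arm than in the Hnrnpk arm and none higher (27 and 0 when adjusted over the list alone; median -0.69; camera adjusted p = 2.3e-24, adjusted p = 0.0674 with an estimated correlation). The largest differences were Krt18 (-2, limma adjusted p = 0.045), Cldn7 (-1.41, limma adjusted p = 0.00584) and Cldn4 (-1.40, limma adjusted p = 0.00983), and Cldn6 was at -1.52 (limma adjusted p = 0.147). In the keratinocyte list 9 of 15 were lower and none higher (12 and 0 when adjusted over the list alone; median -0.87; camera adjusted p = 1.51e-14, adjusted p = 0.0911 with an estimated correlation). Krt5 (-2.44, limma adjusted p = 0.0418), Ivl (-1.74, limma adjusted p = 0.0215), the cornified envelope gene Sprr1a (-1.39, limma adjusted p = 0.0141) and the keratin Krt17 (-1.19, limma adjusted p = 0.0131) led it. These were also the lists that fry called, both downward (adjusted p = 0.00415 for epithelial and 0.00511 for keratinocyte genes). Of the p53 targets 4 of 37 were lower and none higher (6 and 0 when adjusted over the list alone), namely Gdf15 (-1.50, limma adjusted p = 0.0176), Pmaip1 (-0.87, limma adjusted p = 0.0258), Epha2 (-0.86, limma adjusted p = 0.0392) and Gadd45a (-0.78, limma adjusted p = 0.0141). The list median was -0.03 and its mean -0.18 (camera adjusted p = 0.00296, adjusted p = 0.749 with an estimated correlation). Klf4 was higher in the lincRNA-p21 arm (0.66, limma adjusted p = 0.043), the only reprogramming factor called in this contrast. Each called member named for the epithelial, keratinocyte and p53 lists lost its call in this contrast with at least 1 library left out.

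**Figure D3:**
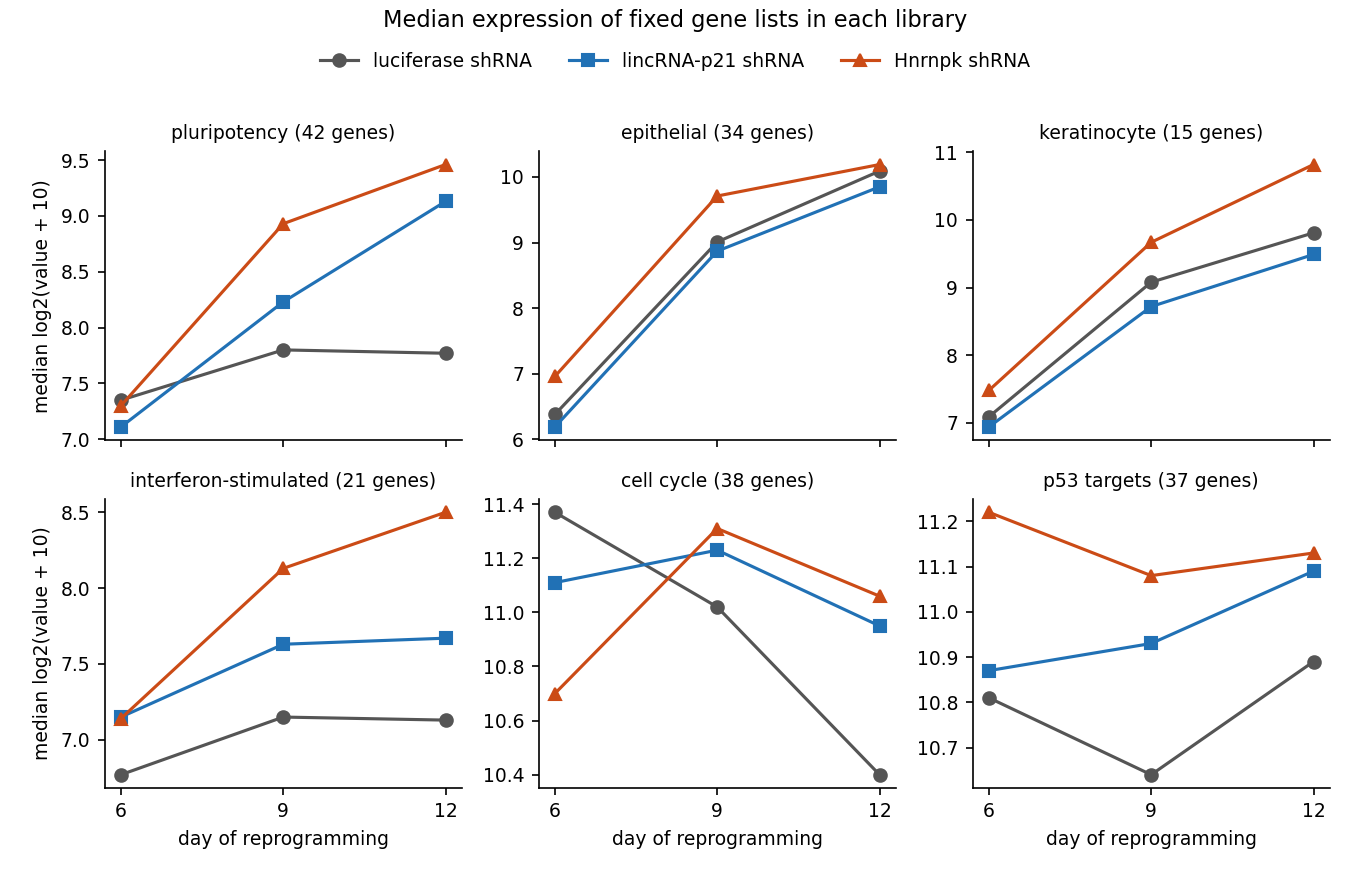
Median log2 value, with 10 added, over the members of 6 gene lists in every library, by arm and day. Each point is the median of 1 library of merged replicates.

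Whether an arm's effect changed with time was tested as its slope over days 6, 9 and 12, in log2 per 3 days. Many cell cycle and pluripotency genes had a called slope in the Hnrnpk arm, and no list test was made on slopes. The mitotic cyclin gene Ccnb1 went from -0.59 on day 6 to 0.79 on day 9 and 1.69 on day 12 relative to control (slope 1.14, SE 0.11, limma adjusted p = 0.0167). In total 1173 genes passed (limma with Benjamini-Hochberg), 634 with a positive and 539 with a negative slope. Of 38 cell cycle genes 29 had a positive slope and none a negative slope (34 and 1 when adjusted over the list alone; median 0.67), among them the survivin gene Birc5 (0.97, limma adjusted p = 0.0167) and the G1 cyclin gene Ccne1 (0.55, limma adjusted p = 0.0384), with E2f2 at 0.55 (limma adjusted p = 0.0965). On the log2 scale the cell cycle median went from 11.37 on day 6 to 10.4 on day 12 in the control arm and from 10.7 to 11.06 in the Hnrnpk arm. Of 42 pluripotency genes 18 had a positive slope (29 when adjusted over the list alone; median 0.74), with Dppa5a (2.66, limma adjusted p = 0.0241), Lin28a (2.25, limma adjusted p = 0.0326) and Tdgf1 (1.58, limma adjusted p = 0.0264) called and Utf1 at 1.66 (limma adjusted p = 0.0805). Of the p53 targets 4 of 37 had a negative slope (6 when adjusted over the list alone; median -0.19). In the lincRNA-p21 arm limma called 0 slopes, with a smallest adjusted p of 0.153 and 2107 genes at unadjusted p under 0.05. Its cell cycle list had 32 positive slopes when adjusted over the list alone (median 0.48) and its pluripotency list 27 positive and 1 negative (median 0.61), with Ccnb1 at 0.66 and Dppa5a at 1.91. Its own cell cycle median went from 11.11 on day 6 to 10.95 on day 12, so those slopes came with the fall in the control arm. Its pluripotency median went from 7.11 to 9.13, against 7.35 to 7.77 in the control arm. Both arms' slopes use the same control libraries, so part of what they share may come from those.

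The time course itself, over all arms, asked which genes change as reprogramming proceeds. From day 6 to day 12, 32 of 34 epithelial, 13 of 15 skin and 31 of 42 pluripotency genes rose, while 2 pluripotency genes fell. Of the fibroblast genes 22 of 45 fell, and of the neural genes 8 of 12. No camera call of these lists held with an estimated correlation. The largest rises included Alox15, a lipoxygenase, and Krt7. Tdgf1 and Dppa5a marked the pluripotent programme. In all 6181 genes passed (limma with Benjamini-Hochberg), 2796 higher and 3385 lower at day 12, of which 1745 differed by at least 2-fold. Most of the called change lay between days 6 and 9. Day 9 against day 6 gave 5008 genes by limma, 2376 higher and 2632 lower, and 2083 of the genes higher and 2444 of those lower at day 12 were already called in the same direction. Independent lists would share 530 and 710, and part of the excess comes from the day 6 libraries that both contrasts use. Day 12 against day 9 gave 82 genes by limma, 66 higher and 16 lower, all of them also called in the same direction between days 6 and 12. Those counts were 833 without day 6 and from 1 to 421 with 1 library left out for day 12 against day 9, and as low as 3062, 3113 and 3185 without the day 9 library of the control, lincRNA-p21 and Hnrnpk arms for day 9 against day 6.

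The largest rises to day 12 by limma with Benjamini-Hochberg were Alox15 (6.61, adjusted p = 1.42e-06, 97.4-fold), the epithelial calcium-binding gene S100a14 (6.06, adjusted p = 4.17e-08, 66.8-fold), the skin protease genes Klk7 (5.67) and Asprv1 (5.55), Krt7 (5.44, adjusted p = 4.17e-08, 43.3-fold), Tdgf1 (5.4), the keratinocyte surface gene Lypd3 (5.38) and Dppa5a (5.34). All but Krt7 stood near or below the added 10 in at least 1 day 6 library. Krt7 stood at 76.5, 135.5 and 47.5 on day 6 and at 4038, 5842 and 2466 on day 12 in the control, Hnrnpk and lincRNA-p21 arms. Tdgf1 ended at 204.5 in the control arm, 3362 in the Hnrnpk arm and 2465 in the lincRNA-p21 arm, and Dppa5a at 44, 2037.5 and 715.5. Among genes not annotated as pseudogenes, the largest falls in the same direction in every arm were Hist1h2ap (-4.50, limma adjusted p = 5.14e-05), the immunoglobulin transporter gene Pigr (-3.45), the homeobox gene Rhox8 (-3.38), Hist1h2ao (-3.20), the oxysterol-binding gene Osbp2 (-3.10), the neural crest factor gene Tfap2b (-3.06), the lysosomal glycoprotein gene Gpnmb (-3.04) and Prr18 (-2.96), a proline-rich protein gene of unknown function. Hist1h2ao was listed at 176.5, 47 and 63 on day 6 and at 0 in every later library. Hist1h2aj, annotated as a pseudogene and named here after its values were seen, was lower still (-5.45, limma adjusted p = 5.76e-06). Hist1h2ap and Hist1h2ao are near-identical copies of 1 histone, between which reads can be shared, so their separate values are uncertain. All 16 of these genes already passed between days 6 and 9, with differences of 1.54 to 4.86 in size, and 6 passed again between days 9 and 12. Krt7 rose by 3.81 and then 1.63 (limma adjusted p = 0.00197) and Alox15 by 4.26 and then 2.35 (limma adjusted p = 0.0113, a call kept in only 4 of 9 with each library left out), while the later step was 1.05 for Tdgf1 (limma adjusted p = 0.392) and -0.36 for Hist1h2ap (limma adjusted p = 0.714).

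By list, 32 of 34 epithelial genes rose and none fell from day 6 to day 12 (33 and 0 when adjusted over the list alone; median 2.68; camera adjusted p = 7.54e-23, adjusted p = 0.076 with an estimated correlation), led after Krt7 by Cldn4 (5.06), Krt18 (4.77) and Cldn7 (4.36). Of 15 keratinocyte genes 13 rose (14 when adjusted over the list alone; median 2.75; camera adjusted p = 3.06e-10, adjusted p = 0.136 with an estimated correlation), led by the keratins Krt6a (4.64) and Krt6b (4.63) and the envelope genes Sprr2d (4.38) and Sprr1a (3.64), all of which have close copies. Of 42 pluripotency genes 31 rose and 2 fell (33 and 2 when adjusted over the list alone; median 1.59; camera adjusted p = 4.37e-09, adjusted p = 0.69 with an estimated correlation), with Lin28a at 5.23 and Utf1 at 4.35. Their median rise was 0.72 in the control arm, 2.00 in the Hnrnpk arm and 2.02 in the lincRNA-p21 arm. Glycolysis genes rose, 15 of 19 with none falling (16 and 0 when adjusted over the list alone; median 1; camera adjusted p = 1.23e-07, adjusted p = 0.197 with an estimated correlation), led by the glucose transporters Slc2a3 (3.23) and Slc2a1 (2.43), the aldolase Aldoc (2.88) and the lactate transporter Slc16a3 (2.51).

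Fibroblast genes fell, 22 of 45 with 2 rising and the same counts when adjusted over the list alone (median -0.51; camera adjusted p = 0.00158, adjusted p = 0.696 with an estimated correlation). Cdh2 (-2.14), the mesenchymal factors Twist2 (-1.71) and Zeb2 (-1.68), and the mesenchymal cadherin Cdh11 (-1.68) fell furthest. Neural genes fell as well, 8 of 12 with none rising and the same counts when adjusted over the list alone (median -0.68; camera adjusted p = 0.00186, adjusted p = 0.136 with an estimated correlation), including Tubb3 (-2.28), Gap43 (-2.16), Nefl (-1.20) and Nefm (-1.13). Of the reprogramming factors Pou5f1 rose (1.43, limma adjusted p = 0.000661) and Myc fell (-0.56, limma adjusted p = 0.025, a call kept in only 5 of 9 with each library left out), with the same counts when adjusted over the list alone. Klf4 was at -0.31 (limma adjusted p = 0.0915) and Sox2 at -0.16 (limma adjusted p = 0.232).

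Differences within each day, with no test, gave the arms' effects without any model. In the Hnrnpk arm 91 genes were at least 2-fold higher and 38 at least 2-fold lower than control on all 3 days. In the lincRNA-p21 arm the counts were 14 and 2, and for lincRNA-p21 against Hnrnpk 10 and 40. The sign was the same on all 3 days for 43.4%, 40.2% and 46.8% of genes in these comparisons, where independent signs would give 25%.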

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

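The tests of mixed-in keratinocytes, of p53 activity and of a raised control value were chosen only after the result was seen. The tests of GC content, of the time course and of the chromosomal neighbourhood were written before they were run, but for patterns already seen in these data.

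A difference between groups under a test of the difference itself marked 4 results. The Hnrnpk effect changed with day for 1173 genes, by a test of the slope. The knockdown arms differed from each other in 409 genes. In that contrast 20 epithelial and 9 keratinocyte genes were lower in the lincRNA-p21 arm. No group held enough libraries for a search for outlying samples.

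The lower epithelial and keratinocyte genes in the lincRNA-p21 arm had a median of -0.80 over the members of both lists. After trends with GC content and transcript length were removed the median was -0.84 (SE 0.08 over genes). Removing these smooth trends shifted all genes by a median of only 0.031, so they do not account for the difference. An SE over genes leaves out variation between libraries. If the Hnrnpk arm were further along the time course, genes that rise late in the control arm should be higher in it. Genes falling from day 9 to day 12 in the control arm lay 0.39 (SE 0.03 over genes) above those rising, and 93.9% of the members rise. A difference in pace may therefore be part of the cause. The members were not taken out of the rising genes, so the 0.39 may partly restate the pattern. Keratinocytes mixed into the Hnrnpk arm could also give it. The excess over control at days 6 and 12, in deposited values, correlated with a rho of 0.7 across the list. Genes with high values can have a large excess on both days without mixed-in cells, so the rho cannot tell these apart. In the control arm 14 of 15 members were above 20 on day 12, so this stays open.

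Trp53cor1 was lower in the Hnrnpk arm, whose hairpin does not target it. Lower p53 activity would lower the p53 targets. None of 37 was called lower and their median was 0.21 (SE 0.07 over genes), which argues against lower p53 activity as the cause. The list was not called by camera with an estimated correlation (adjusted p = 0.471) or by fry (adjusted p = 0.0512). It therefore does not settle p53 activity at Trp53cor1 itself. A fall of the whole neighbourhood was not seen either, as the 14 other genes within 500 kb had a median of 0 (SE 0.1 over genes). Among them, however, Pi16 (-0.87, limma adjusted p = 0.00516) and Mtch1 (-0.4, limma adjusted p = 0.0407) fell and Pim1 rose (0.48, limma adjusted p = 0.027). A raised value in the control arm remains possible, because the knockdown arms differed by only -0.31 (SE 0.15, limma adjusted p = 0.318). Hnrnpk loss, another effect of its hairpin and a high control arm cannot be separated with 1 arm per target and 1 control hairpin.

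Other splits of the libraries were tried for each count. For the lincRNA-p21 arm (1 gene), the Hnrnpk arm (1570), the knockdown arms against each other (409), day 12 against day 6 (6181), day 9 against day 6 (5008) and day 12 against day 9 (82), the 10 splits are too few for a share under 0.05. In each, 1 split of 10 reached the count, the real grouping, and the highest other gave 0. These splits were not held within days for the arms, or within arms for the days. Many therefore break the pairing, and their 0 says little. For the Hnrnpk slope the real value was 1173 and the highest other of 4 exchanges 0, again too few. For the lincRNA-p21 slope all 4 of 4 gave 0. For both knockdowns against control (787 genes), 2 of 27 relabellings reached the count, and the highest other, 1381, set the Hnrnpk arm apart from the rest. That count may therefore reflect the Hnrnpk arm more than a shared effect.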

How the results depend on the processing

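None of the alternatives here was chosen after the result was seen, and all were fixed before the data were examined. Other scalings (quantile or median-ratio) moved no count by over 1.5 times, but the columns already appear to share a scale, so these could change little. The called genes that were followed by name kept their direction in each alternative run for them. Klf4 between the knockdown arms, Hist1h2aj, Fgf5, Eomes, Sox1 and the Trp53cor1 neighbours Pi16, Mtch1 and Pim1 were not followed. The slope genes had no libraries left out.

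The counts of called genes moved as follows, and the cause was not tested except where fewer libraries or degrees of freedom enter by construction. For lincRNA-p21 against control (1 gene), an added value of 50, no day term and only the 6 libraries compared each gave 0 by limma (1695, 321 and 1964 at unadjusted p under 0.05), and no trend gave 13. For Hnrnpk against control (1570), no day term gave 1 and only the 6 libraries 330. For lincRNA-p21 against Hnrnpk (409) these gave 1 and 646. For both knockdowns (787) no day term gave 0 (974 at unadjusted p under 0.05). For day 12 against day 9 (82), an added value of 1 gave 50, no arm term 0 (854 at unadjusted p under 0.05) and only the 6 libraries 833. For the Hnrnpk slope (1173) no trend gave 596. The correlation of the knockdown effects was 0.616 as Spearman rho (simulated 0.473).

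An estimated correlation left 0 list calls in all 4 contrasts, where camera with a preset correlation had 10 (lincRNA-p21), 8 (Hnrnpk), 5 (between knockdowns) and 9 (day 12 against day 6). The test fry gave 1, 5 and 2 in the first 3. Genes past 2-fold on all 3 days numbered 16, 129 and 50 for lincRNA-p21, Hnrnpk and their contrast. An added value of 50 gave 0, 40 and 12, and a fold of 1.5 gave 116, 497 and 326.

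With days left out, counts ranged from 0 to 175 (lincRNA-p21), 25 to 3001 (Hnrnpk), 0 to 649 (between knockdowns) and 2 to 1965 (both), and were 4498 (day 12 against 6), 4526 (day 9 against 6) and 833 (day 12 against 9). With 1 library left out they ranged from 0 to 92, 559 to 2045, 4 to 959, 5 to 1374, 4321 to 6225, 3062 to 5605 and 1 to 421 in the same order. Where this leaves an arm with fewer libraries, their spread is assumed to be that of the other arms. Calls of lists ranged from 5 to 9 (lincRNA-p21), 7 to 12 (Hnrnpk) and 5 to 7 (between knockdowns), and stayed at 9 for day 12 against day 6. The slopes have no residual degrees of freedom with a day left out and were not run.

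Some small differences changed sign. Over the libraries and days left out Cdkn1a ranged from -0.08 to 0.11 (lincRNA-p21), -0.08 to 0.13 (Hnrnpk), -0.06 to 0.06 (between knockdowns) and -0.08 to 0.11 (both), Ddx3y from -0.02 to 0.17 (Hnrnpk), and Hist1h2ap from -0.63 to 0.04 (day 12 against 9). The camera direction of 4 lists turned with a day left out. Their medians ranged from 0.03 to 0.21 (fibroblast, lincRNA-p21), 0.03 to 0.47 (cell cycle, lincRNA-p21), -0.2 to 0.02 (methylation machinery, Hnrnpk) and -0.08 to 0.27 (fibroblast, Hnrnpk).

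With each library left out in turn, 30 of the 55 called genes followed by name for Hnrnpk kept their call every time, as did 38 of 39 for day 12 against day 6 (all but Myc), 4 of 4 for day 9 against day 6, 1 of 2 for day 12 against day 9, 1 of 3 for both knockdowns, 0 of 12 between the knockdowns and 0 of 1 for lincRNA-p21. With the depth unknown, no limit of detection can be given for low genes.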

Other observations

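Beyond the lists of the report, 2 of 10 early lineage genes rose and 1 fell in the Hnrnpk arm, a camera call that was lost with an estimated correlation and that fry did not make (adjusted p = 0.0882). Fgf5, a growth factor of the primed epiblast (1.90, limma adjusted p = 0.0332), and Eomes, a factor of mesendoderm (1.49, limma adjusted p = 0.0136), rose, and the neural factor gene Sox1 fell (-1.67, limma adjusted p = 0.017). The list gave 5 and 1 when adjusted over the list alone, with a median of 0.47 (camera adjusted p = 0.0246, adjusted p = 0.483 with an estimated correlation). In the lincRNA-p21 arm its median was 0.38 with none of 10 called (2 higher when adjusted over the list alone; camera adjusted p = 0.031, adjusted p = 0.847 with an estimated correlation). Glycolysis genes had a median of -0.20 in the Hnrnpk arm, 1 of 19 higher and 2 lower (1 and 3 when adjusted over the list alone; camera adjusted p = 0.0465, adjusted p = 0.527 with an estimated correlation). Under quantile normalization the camera adjusted p was 0.0745 for glycolysis and the same for early lineage genes. Without day 6 it was 0.322 for glycolysis, and without day 12 it was 0.126 for early lineage genes, so these calls were lost.

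Other lists of the lincRNA-p21 arm lay above other genes by camera with no member called. They were senescence (22 genes, 1 higher when adjusted over the list alone, median 0.28, adjusted p = 0.0021, adjusted p = 0.564 with an estimated correlation), oxidative phosphorylation (28 genes, 0 when adjusted over the list alone, median 0.14, adjusted p = 0.00727, adjusted p = 0.871 with an estimated correlation) and cell cycle (38 genes, 0 when adjusted over the list alone, median 0.19, adjusted p = 0.00898, adjusted p = 0.871 with an estimated correlation). Fibroblast genes (45, 2 higher when adjusted over the list alone, median 0.12, camera adjusted p = 0.031, adjusted p = 0.871 with an estimated correlation) and p53 targets (37, 0 when adjusted over the list alone, median 0.11, camera adjusted p = 0.031, adjusted p = 0.868 with an estimated correlation) did so as well. The call of the senescence, fibroblast, oxidative phosphorylation and p53 lists was lost without day 6, and that of the cell cycle list without day 9 or day 12. Without day 12 only 5 lists were called in this arm, so other list calls were lost there as well.

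Between the knockdown arms interferon genes were lower in the lincRNA-p21 arm, 3 of 21 (9 when adjusted over the list alone; median -0.53; camera adjusted p = 3.32e-09, adjusted p = 0.459 with an estimated correlation). Pluripotency genes were lower too, 2 of 42 (3 when adjusted over the list alone; median -0.39; camera adjusted p = 1.32e-05, adjusted p = 0.808 with an estimated correlation). From day 6 to day 12 ribosomal protein genes rose, 8 of 15 with 1 falling (9 and 1 when adjusted over the list alone; median 0.58; camera adjusted p = 0.00322, adjusted p = 0.69 with an estimated correlation). Interferon genes had 9 of 21 higher and 3 lower, the same when adjusted over the list alone (median 0.51; camera adjusted p = 0.0158, adjusted p = 0.696 with an estimated correlation). Oxidative phosphorylation genes had 10 of 28 higher and 1 lower, the same when adjusted over the list alone (median 0.26; camera adjusted p = 0.0184, adjusted p = 0.767 with an estimated correlation).

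The remaining lists were not called in the Hnrnpk arm. Their medians were 0.15 for cell cycle, where no member was called (camera adjusted p = 0.256), 0.01 for apoptosis (camera adjusted p = 0.976), 0.05 for oxidative phosphorylation (camera adjusted p = 0.281), -0.05 for ribosomal proteins (camera adjusted p = 0.754), -0.03 for endothelial genes (camera adjusted p = 0.887, 1 higher and 1 lower, also when adjusted over the list alone) and -0.14 for hnRNP paralogs (camera adjusted p = 0.282, 1 of 23 lower, 0 when adjusted over the list alone). Lists with fewer than 5 members were read as values, with medians of 0 for 4 adipocyte genes, 0.30 for 3 macrophage genes and 0.32 for 2 histone genes of the fixed list, and none of the mitochondrially encoded genes was in the table.

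For histones, the tests of the cell cycle list, its values by arm and the test of reads moved between copies were chosen only after the result was seen. The test of small RNAs was written before it was run, but for a pattern already seen in these data. The fixed histone list held only 2 genes in the table, of which 1 rose and none fell from day 6 to day 12, the same when adjusted over the list alone (median 0.22). Of all 20 histone genes by name, gathered outside that list after their values were seen and given no list test, 14 were lower and 2 higher at day 12 than at day 6, with a median of -1.32. The cell cycle list had a median of -0.16 (SE 0.07) over all arms. By arm the cell cycle and histone medians were 0.33 and -1.47 in the Hnrnpk arm and -0.02 and -1.45 in the lincRNA-p21 arm, so lower proliferation does not account for the fall there. In the control arm they were -0.84 and -0.78, so there it may. Reads moved among the 6 H2A genes of cluster 1 in the table do not account for the fall. Their sum was 11.9 to 50.9 times higher on day 6 in every arm. Reads moved to copies absent from the table would lower this sum too, so that stays open. More RNA without a poly(A) tail in the day 6 libraries could give such a fall. Only 3 small RNAs were in the table, with a median of 0.13 (SE 0.79 over genes), so that explanation stays open.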
